A study of Mus musculus with 6 samples.

How the data were processed

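Polyadenylated RNA was sequenced from primary mouse bone marrow macrophages that had been driven towards osteoclasts, the multinucleate cells that resorb bone. Per the labels' protocols, marrow was flushed from the hindlimb bones of mice aged 8 weeks and expanded with 10 ng/mL M-CSF, the macrophage growth factor. After a passage the cells received 30 ng/mL M-CSF together with 50 ng/mL RANKL, the cytokine that starts osteoclast formation, for 48 hours. The control cells carried floxed Slc11a2 alleles only, and the conditional knockout cells (cKO) carried the same alleles and Cre recombinase under the lysozyme M promoter, which is active in the myeloid lineage. Each genotype had 3 libraries. The series design says that the controls were litters of the knockout mice. Whether each library came from its own mouse or culture is not given in the sources used here, so p-values measure the spread between these libraries, which may be technical in part.

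Per the labels' protocols, libraries were made from 5 µg of total RNA with a RIN above 7.0 by oligo(dT) selection and the dUTP method, which marks the strand, with inserts near 300 bp. The submitters' processing notes name cutadapt 1.9 and the genome build mm10. The aligner, the counting program, the annotation release and whether counting used the strand are not given in the sources used here. Genes that overlap another gene, or that share sequence with copies elsewhere, are therefore uncertain in these counts. The deposited files hold whole-number read counts per gene, with no normalization, per the file headers. They also hold FPKM values computed by the authors, per the file headers, which were used here only to check the counts: the length implied by counts and FPKM varied between libraries by a median of 0.062% over 8655 genes with at least 500 reads. All 6 files list the same 26699 genes, each with at least 1 read in some library, and no row names anything other than a gene. Of the gene identifiers, 99.76% were found in GENCODE release M21 and 89.96% had the same coordinates and strand there; coordinates below are those of the files, on mm10. There are 102 rows whose symbol is shared with another row, and these are named here by symbol and identifier.

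Total counts per library ranged from 49720701 to 57797282, so that a single read was worth 0.0173 to 0.0201 CPM, the count scaled to a common library total. Pairs of libraries of the same genotype differed by far more than sampling noise, with chi-square values of 19.2 to 44.1 per degree of freedom, so no library appears to have been deposited again under another name. Genotypes were compared with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and a quasi-likelihood F test with robust estimation was applied to the 3 libraries of each genotype. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p below 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of its F statistic. Levels are CPM after TMM scaling, given as mean ± SD over 3 libraries.

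Before the data were examined, 39 gene lists were fixed, and so were the main test and most of the alternatives. The lists cover osteoclast fusion and transcription factors, bone resorption, negative regulators of osteoclast differentiation, iron handling, heme and iron-sulfur synthesis, the respiratory chain, mitochondrially encoded genes, the TCA cycle, glycolysis, hypoxia, NRF2 and glutathione, ferroptosis, ATF4 targets, S phase, G2 and M phase, interferon response, inflammatory and NF-kB genes, alternative activation, macrophage identity, MHC class II, cholesterol synthesis, lipid uptake and efflux, lysosome and vacuolar ATPase, autophagy, mitochondrial biogenesis, p53 and apoptosis, immediate early genes, metal transport, and markers of neutrophils, erythroid cells, B cells, T and NK cells, stroma, endothelium, dendritic cells, mast cells, megakaryocytes and adipocytes. Of the 8 adipocyte genes fewer than 3 were measured, so 38 lists were tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01. Each test was repeated with an estimated correlation and with fry. A list adjusted over the list alone has its Benjamini-Hochberg values computed within its own members.

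Genes are named by a rule fixed beforehand. Slc11a2, Lyz2, Tfrc, Slc40a1, Fth1, Nfatc1, Acp5, Ctsk, Mmp9, Dcstamp and Atp6v0d2 are always named. The 10 largest rises and the 10 largest falls are named among genes with an official symbol, complete separation of the 3 libraries of each genotype, an adjusted p below 0.05 and a mean of at least 5 CPM in the higher group. Up to 4 members of each list described are named, by smallest raw p; for marker lists of other cell types only members that passed were taken. Genes named outside this rule are said to have been chosen after their values were seen.

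The tests were tried on simulated data first. Counts for the real genes were drawn with 200 genes changed by known folds, 50 per fold size. For the comparison of cKO with control over 16408 genes, edgeR recovered 40% of the genes changed 1.25-fold, 80% at 1.5-fold, 98% at 2-fold and 100% at 4-fold. There were 17 false calls among 176, above the nominal rate, and DESeq2 made 36 among 208. A list shifted by -0.2 on the log2 scale was called, and 0 of the other lists were. The simulated genes were drawn independently of each other, whereas the estimated correlation within that list was 0.27 in the real data. The simulation therefore does not measure false list calls under such correlation. Alternatives were DESeq2 1.42.0, limma-voom with and without sample weights, DESeq2 size factors in place of TMM, no filter and a filter at 10 times the minimum (100 reads, total of 150), the replicate number as a block, and each library left out in turn. After the data were seen, a fit was added in which each library's trend of log counts on transcript length and GC content was removed by loess (span 0.3). An enrichment test of the GO, KEGG and Reactome terms printed in the files was added as well. Files were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.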

Results

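The transcriptome of RANKL-treated bone marrow macrophages was compared between Slc11a2-floxed control cells and cells in which Cre recombinase from the lysozyme M locus deletes Slc11a2 (cKO). Slc11a2 encodes DMT1, a transporter that moves ferrous iron and other divalent metals into the cytosol. The comparison asks how gene expression during osteoclast formation differs between these genotypes. The control cells carried no Cre, so effects of Cre and of its insertion in Lyz2 cannot be told apart from those of Slc11a2 loss. There were 3 control and 3 cKO libraries, all taken after 48 hours with 50 ng/mL RANKL. Total counts were 52989755, 57797282 and 57663659 in control replicates 1 to 3 and 49720701, 55279336 and 53061642 in cKO replicates 1 to 3. Between 20804 and 21837 genes had at least 1 read per library. Correlations of log2 CPM were 0.980 to 0.983 within a genotype and 0.977 to 0.979 between genotypes. The first principal component held 28.6% of the variance, with the control libraries at -38.4, -23.2 and -23.8 and the cKO libraries at 29.7, 31.1 and 24.6.

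Slc11a2 transcripts were lower in every cKO library but far from absent. The gene (ENSMUSG00000023030, chromosome 15, 100387898 to 100424092) stood at 118, 110 and 118 CPM in control replicates 1 to 3 and at 78.3, 82.8 and 87.4 CPM in cKO replicates 1 to 3. Its log2 fold change was -0.48 with a standard error of 0.06 (edgeR quasi-likelihood adjusted p = 0.00219), a fall of 28.3%. Counts per gene do not separate the floxed exons from the rest of the transcript, so this value does not measure the efficiency of deletion. Lyz2, the lysozyme gene whose locus carries the Cre insertion (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), fell from 17110 ± 1577 to 7783 ± 96.8 CPM (mean ± SD, n = 3 per genotype). Its log2 fold change was -1.14 ± 0.08 (SE), with an adjusted p of 9.39e-06. Both directions match the labels of all 6 libraries.

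**Figure D1:**
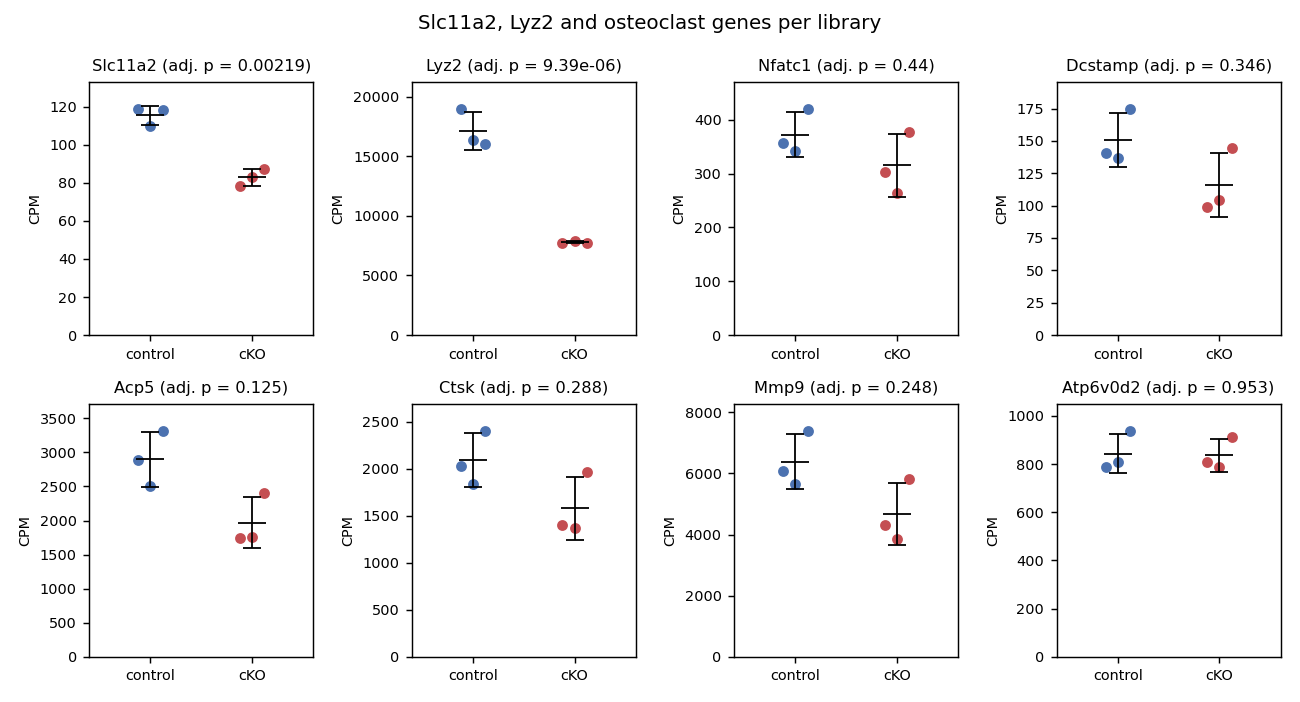
TMM-normalised CPM (linear axes from 0) of 8 genes in each library, with points for single libraries and bars for mean ± SD of 3 libraries per genotype; adjusted p-values are from the edgeR test over all genes. Slc11a2 and Lyz2 separate the genotypes, as does Acp5, which did not pass the test, whereas Nfatc1, Dcstamp, Ctsk, Mmp9 and Atp6v0d2 overlap between them.

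Of 16843 genes tested, 407 differed between genotypes (2892 at an unadjusted p under 0.05), 229 of them higher and 178 lower in cKO cells. Most differences were small: the median size among called genes was 0.44 on the log2 scale, and 61 genes changed at least 2-fold. Of these 61 genes, 48 were higher and 13 lower, and 20 stayed below 1 CPM in both genotypes. All 407 called genes had fully separated genotypes, as did 22.5% of all tested genes, against 10% by chance for 3 libraries against 3. The number of calls moved strongly with single libraries: it was 91, 166 and 116 without control replicate 1, 2 or 3, and 59, 235 and 624 without cKO replicate 1, 2 or 3. It was 874 with DESeq2 and 704 with limma-voom and sample weights.

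The 10 largest rises among genes with an official symbol and at least 5 CPM went from 1.11 to 1.93 on the log2 scale. Predicted Gm gene models, which the naming rule leaves out, rose by more, with Gm42047 (chosen after its values were seen) at 4.94 ± 0.12. Ccr2, the receptor for the monocyte chemoattractant CCL2 (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557), rose from 3.69 ± 0.27 to 14.1 ± 2.83 CPM, a log2 fold change of 1.93 ± 0.16 (SE, adjusted p = 7.9e-05). Itgad, the integrin CD11d, rose by 1.53 ± 0.22. The neutrophil granule genes Ngp and Ltf rose by 1.42 ± 0.14 and 1.33 ± 0.13, Ngp from 7.79 ± 1.15 to 20.8 ± 2.81 CPM, and S100a9, a subunit of calprotectin, rose by 1.16 ± 0.17. The other large rises were in Slc15a2, a peptide transporter (1.33 ± 0.14), Camk2b, a calmodulin-dependent kinase (1.32 ± 0.15), Tubb3, a beta-tubulin (1.31 ± 0.18), the orphan receptor gene Gprc5c (1.16 ± 0.18) and Mamdc2 (1.11 ± 0.08). Mamdc2 was the most abundant of these 10 genes, at 109 ± 11.3 CPM in control and 234 ± 17.9 CPM in cKO cells. The call of Gprc5c was lost without cKO replicate 1 (adjusted p = 0.0639); the other 9 genes were called in all 6.

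Beside Lyz2, the falls included 2 pattern-recognition lectins and 2 features of uncertain assignment. Clec4n, which encodes the fungal receptor Dectin-2 (ENSMUSG00000023349, chromosome 6, 123229843 to 123247021), fell from 397 ± 43.0 to 206 ± 13.9 CPM, a log2 fold change of -0.95 ± 0.08 (SE, adjusted p = 0.000105). Its neighbour Clec4e, encoding Mincle, fell from 22.6 ± 1.29 to 13.9 ± 3.29 CPM (adjusted p = 0.0415). The remaining falls were in the semaphorin gene Sema3c (-1.06 ± 0.22), Il1f9, an interleukin-1 family cytokine also called IL-36 gamma (-0.68 ± 0.14), Akr1c12, an aldo-keto reductase (-0.67 ± 0.12), Atp5g1, a subunit of the ATP synthase c-ring (-0.66 ± 0.12), and Slc24a5, a cation exchanger (-0.64 ± 0.15). Erdr1 (chromosome X, 170009659 to 170019281) stood at 10.1 ± 1.27 CPM in control and 0.92 ± 0.02 CPM in cKO cells (-3.46 ± 0.17). The Ndor1 row ENSMUSG00000115018 (chromosome 2, 25244819 to 25246863) stood at 5.91 ± 1.30 and 0.31 ± 0.16 CPM (-4.25 ± 0.35). Erdr1 lies in the pseudoautosomal region and this Ndor1 row overlaps another row of the same symbol and strand, so the assignment of reads to both is uncertain. That other row, Ndor1_ENSMUSG00000006471, chosen after its values were seen, was called in the opposite direction, from 24.9 ± 1.30 to 33.7 ± 3.69 CPM (0.44 ± 0.09, adjusted p = 0.0302, but 0.144 without cKO replicate 1). The calls of Clec4n, Erdr1 and the Ndor1 row held in all 6 fits that leave out a library, whereas those of the other 6 genes were lost in 3 to 6 of them. All 6 were lost without control replicate 3 or cKO replicate 1, where the adjusted p of Sema3c was 0.19 without the latter.

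Osteoclast genes leaned lower in cKO cells, mainly in replicates 1 and 2, and how many passed depended on the tool. In the lists of fusion and transcription factors and of bone resorption, edgeR called 3 and 2 genes and DESeq2 6 and 8. An unadjusted p under 0.05 was found for 7 and 16. Of 33 genes for osteoclast fusion and transcription factors, 0 rose and 3 fell: Relb and Nfkb2, the pair of the non-canonical NF-kB pathway, and Clec5a, a DAP12-coupled receptor. Relb fell from 42.0 ± 2.18 to 32.2 ± 2.89 CPM (-0.38 ± 0.08 SE, adjusted p = 0.0321). The master regulator Nfatc1 had a log2 fold change of -0.24 ± 0.14 (adjusted p = 0.44), the fusion gene Dcstamp -0.38 ± 0.17 (0.346), Tfec -0.30 ± 0.08 (0.09) and the fusion-related pump subunit Atp6v0d2 -0.01 ± 0.08 (0.953). The sign of Atp6v0d2 depended on the filter, the library left out and the removal of the length trend. Of 30 genes of bone resorption, 1 rose and 1 fell: Sort1, a sorting receptor, rose by 0.55 ± 0.06 and Atp6v1c1, a proton pump subunit, fell by 0.42 on the log2 scale. Acp5, the tartrate-resistant acid phosphatase, stood at 2902 ± 404 CPM in control and 1971 ± 372 CPM in cKO cells (-0.56 ± 0.15, adjusted p = 0.125), with Ctsk at -0.40 ± 0.17 (0.288), Mmp9 at -0.45 ± 0.17 (0.248) and Ostm1 at -0.20 ± 0.06 (0.101). Of these genes, Acp5, Mmp9, Ctsk, Dcstamp and Nfatc1 were called in 2 alternatives, with the replicate number as a block and without cKO replicate 3. Without that library Acp5 reached an adjusted p of 0.00438, Mmp9 0.0105, Ctsk 0.00994, Dcstamp 0.0133 and Nfatc1 0.045. Over all alternatives the adjusted p ranged from 0.000827 to 0.307 for Acp5, 0.00212 to 0.495 for Mmp9, 0.00404 to 0.535 for Ctsk, 0.00574 to 0.579 for Dcstamp and 0.0362 to 0.7 for Nfatc1. The call of Sort1 held without any library in turn, while those of Relb, Clec5a, Nfkb2 and Atp6v1c1 held only without cKO replicate 3 and reached adjusted p of 0.188, 0.218, 0.234 and 0.175 without cKO replicate 1.

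Both lists moved lower as sets with camera, with medians of -0.14 for fusion and transcription factors (adjusted p = 0.000215) and -0.27 for bone resorption (adjusted p = 6.84e-06). The shift was largest in cKO replicates 1 and 2. Relative to the control mean, cKO replicate 3 had a mean log2 level of -0.027 in the first list and -0.014 in the second. These lie within the control ranges of -0.047 to 0.094 and -0.075 to 0.057. Control replicate 3 was the highest control in both lists, and without it the medians were -0.076 and -0.175. Without cKO replicate 2 they were -0.073 and -0.192, and without cKO replicate 3 -0.257 and -0.419. Neither call held with an estimated correlation, where both had an adjusted p of 0.45. Adjusted over the list alone, 6 genes of the first list fell, and 1 rose and 5 fell in the second. Among 25 negative regulators of osteoclast differentiation, Bcl6 rose by 0.39 ± 0.06 (adjusted p = 0.00876) and Nfkbia, the inhibitor of NF-kB, fell by 0.39 on the log2 scale (adjusted p = 0.0316). Dusp1 was at -0.39 ± 0.10 (0.0542) and Rgs10 at -0.23 ± 0.06 (0.0588). That list had a median of -0.02 and was not called (adjusted p = 0.429), and 2 rose and 4 fell when adjusted over the list alone. Without cKO replicate 1 the adjusted p was 0.0875 for Bcl6 and 0.203 for Nfkbia, and both calls were also lost without control replicate 1 or 3, and that of Nfkbia without cKO replicate 2.

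The list of iron-handling genes, which leaves out Slc11a2 itself, held no call. Of its 36 measured genes for iron uptake, storage and export, 0 rose and 0 fell with edgeR, also when adjusted over the list alone, and the median was -0.04 (camera adjusted p = 0.311). At an unadjusted p under 0.05 there were 8 genes, and DESeq2 called 2. The transferrin receptor gene Tfrc stood at 441 ± 64.2 CPM in control and 388 ± 50.7 CPM in cKO cells (-0.18 ± 0.12 SE, adjusted p = 0.49). The iron exporter gene Slc40a1 had a log2 fold change of -0.14 ± 0.08 (0.393) and the ferritin heavy chain gene Fth1 -0.02 ± 0.09 (0.939), whose sign depended on the fit. The ferritin light chain gene Ftl1 was at -0.25 ± 0.08 (0.133), Hmox1, the heme oxygenase, at -0.20 ± 0.07 (0.151), Blvra at -0.25 ± 0.07 (0.0982) and Bdh2 at -0.56 ± 0.22 (0.215). Among 37 genes for heme synthesis and iron-sulfur cluster assembly, 1 rose and 1 fell. Ndor1, which also belongs to the list, was left out because its symbol is shared by 2 rows. Alas1, which catalyses the entry step of heme synthesis, rose from 342 ± 17.7 to 423 ± 11.6 CPM (adjusted p = 0.0233), and Iscu, the scaffold for iron-sulfur clusters, fell from 49.7 ± 2.24 to 40.0 ± 1.22 CPM (adjusted p = 0.0316). Nubp2 (-0.28 ± 0.09) and Ciao2a (-0.27 ± 0.08) did not pass. The list had a median of -0.15 and a camera adjusted p of 0.00106, which became an adjusted p of 0.41 with an estimated correlation; adjusted over the list alone, 1 rose and 1 fell. The calls of Alas1 and Iscu were lost without control replicate 1 or 3 or cKO replicate 1 or 2, with adjusted p of 0.144 and 0.186 without cKO replicate 1, and that of Iscu also without control replicate 2.

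Nuclear genes of the respiratory chain were lower throughout in cKO cells. All 49 genes of complexes I, II and III had negative log2 fold changes, with a median of -0.25; 0 rose and 5 fell, and 26 fell when adjusted over the list alone. Sdhb and Sdhc, subunits of succinate dehydrogenase, had log2 fold changes of -0.43 ± 0.07 and -0.31 ± 0.07, the Rieske iron-sulfur protein gene Uqcrfs1 -0.43 ± 0.08, and the complex I gene Ndufa10 -0.32 ± 0.07. All 26 measured genes of complex IV and ATP synthase were negative too, with a median of -0.27; 0 rose and 6 fell, and 23 fell when adjusted over the list alone. Besides Atp5g1 they included Cox5a (-0.33 ± 0.07), Cox6a1 (-0.28 ± 0.06) and Atp5g3 (-0.41 ± 0.08). Of 18 TCA cycle genes, all negative with a median of -0.22, Idh3a fell (-0.36 ± 0.08, adjusted p = 0.0414), and 13 fell when adjusted over the list alone; Mdh2 (-0.37 ± 0.09, 0.0522), Sucla2 (-0.23 ± 0.06) and Suclg1 (-0.23 ± 0.07) did not pass. Of the 13 genes encoded in mitochondrial DNA, 1 fell, mt-Co3 (-0.30 ± 0.06, adjusted p = 0.0307), and the median was -0.03; mt-Nd3, mt-Co1 and mt-Nd1 were at -0.19 ± 0.06, -0.14 ± 0.07 and -0.14 ± 0.07. Adjusted over the list alone, 1 mitochondrially encoded gene fell.

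By camera, the adjusted p was 4.83e-17 for complexes I to III, 1.84e-18 for complex IV and ATP synthase, 1.55e-09 for the TCA cycle and 0.0973 for mitochondrially encoded genes. With an estimated correlation the first 3 had an adjusted p of 0.309, 0.325 and 0.41, and the last 0.692. The libraries also carried a trend over transcript length, but these lists did not follow it library by library. In the shortest genes, the median deviation from the mean of the 6 libraries was -0.007 in cKO replicate 2 and -0.086 in cKO replicate 3. The nuclear respiratory chain genes were lower in cKO replicate 2, at a mean of -0.277 against -0.202 relative to the control mean. Among 9498 genes above 3 log2 CPM, the log2 fold change had a Spearman correlation with transcript length of 0.32 across genes, which are not independent replicates. In 10 equal groups by length, the median was -0.12 in the group of shortest genes and 0.05 in that of the longest, and the respiratory chain genes were short, with a median of 1141 bp against 3584 bp. With the trend over length and GC content removed, a fit added after the data were seen, the medians were -0.19 for complexes I to III, -0.20 for complex IV and ATP synthase and -0.18 for the TCA cycle; 3, 3 and 0 of their genes fell. In that fit the mitochondrially encoded genes had a median of -0.01. Without control replicate 1 or 2 or cKO replicate 1 their list was called (0.0435, 0.0252 and 0.00511), over a range of 0.00511 to 0.931. Each of the named calls in these lists was lost in 3 to 5 of the 6 fits that leave out a library, always without control replicate 1 or 3 or cKO replicate 1, where the adjusted p was 0.123 for Sdhb and 0.241 for Idh3a without the last.

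**Figure D2:**
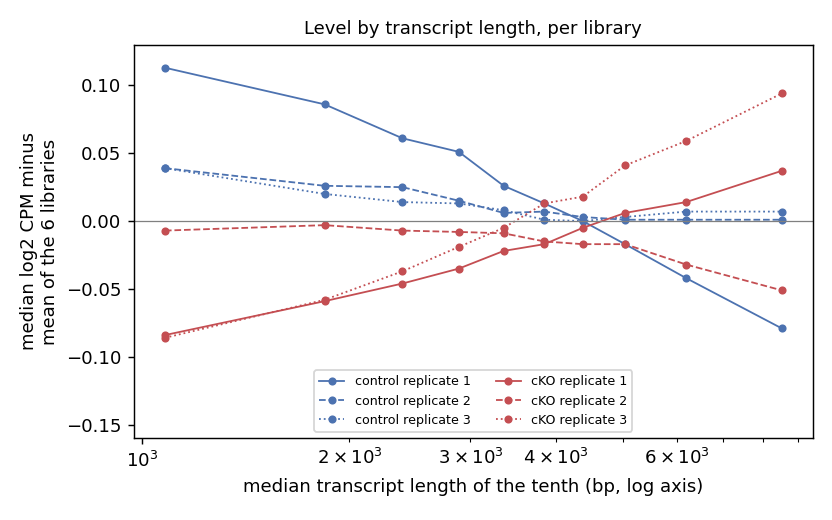
Median deviation of log2 CPM from the mean of the 6 libraries (vertical axis) in 10 equal groups of 9498 genes ordered by transcript length (bp, log axis), 1 line per library. Short genes are relatively higher in control replicate 1 (0.113) and lower in cKO replicates 1 (-0.084) and 3 (-0.086).

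Some antioxidant and proton pump genes were lower in cKO cells. Of 27 genes of the NRF2 and glutathione list, 0 rose and 7 fell. They included Gsta3, a glutathione transferase (-0.60 ± 0.09), Gclm, the modifier subunit of the enzyme that starts glutathione synthesis (-0.33 ± 0.06), the quinone reductase gene Nqo1 (-0.46 ± 0.08) and malic enzyme Me1 (-0.34 ± 0.07). The list's median was -0.11 with a camera adjusted p of 6.25e-07, and an adjusted p of 0.309 with an estimated correlation; 9 genes fell when adjusted over the list alone. Of 34 genes of the lysosome and vacuolar ATPase list, 0 rose and 7 fell, all 7 of them subunits or accessory proteins of the vacuolar proton pump, which acidifies lysosomes and the resorption space under osteoclasts. Atp6v1h fell from 165 ± 10.4 to 120 ± 12.4 CPM (-0.45 ± 0.08, adjusted p = 0.0115), and Atp6v1g1, Atp6v1e1 and Atp6v0d1 were at -0.34 ± 0.06, -0.33 ± 0.07 and -0.26 ± 0.06. The list's median was -0.11 (camera adjusted p = 5.97e-05, and an adjusted p of 0.45 with an estimated correlation), and 2 rose and 13 fell when adjusted over the list alone. With a library left out, this median ranged from -0.072 without control replicate 1 to -0.147 without control replicate 2. With the length and GC trend removed, 1 rose and 5 fell in the NRF2 list (median -0.09, from -0.11) and 3 fell in the lysosome list (median -0.104, from -0.112), so fewer calls do not mean that the shift was lost. All 8 named calls were lost without cKO replicate 1, at adjusted p of 0.0663 for Gsta3 to 0.191 for Atp6v0d1, and 6 of them without control replicate 1, Gsta3 and Nqo1 being the exceptions.

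Further lists covered metabolism and stress. Of 20 glycolysis genes, Pgk1 fell (-0.30 ± 0.06, adjusted p = 0.0236), and Eno2 (0.80 ± 0.20), Tpi1 (-0.27 ± 0.07) and Eno1 (-0.25 ± 0.07) did not pass; the median was -0.11, the camera adjusted p 0.0141 and the adjusted p 0.484 with an estimated correlation. Of 28 hypoxia genes, Bnip3, a mitophagy receptor, fell (-0.35 ± 0.07, adjusted p = 0.0236), with Hif1a at -0.26 ± 0.07, Bnip3l at 0.19 ± 0.06 and Slc2a1 at -0.18 ± 0.06; the list was not called (0.155). Bnip3 was also the only call among 27 autophagy and mitophagy genes, where Gabarap (-0.21 ± 0.06), Bnip3l and Gabarapl2 (-0.28 ± 0.08) did not pass and the list was not called (0.155). None of 18 ferroptosis genes was called with edgeR, Alox5 (-0.58 ± 0.14) and Hspb1 (-0.43 ± 0.12) having the smallest p, with Ptgs2 at -0.29 ± 0.11 and Vdac2 at -0.15 ± 0.06; 7 had an unadjusted p under 0.05, DESeq2 called 2, and 2 fell when adjusted over the list alone; the list's median was -0.09, with a camera adjusted p of 0.00362 and an adjusted p of 0.309 with an estimated correlation. None of 19 genes of mitochondrial biogenesis and dynamics was called (median -0.10, camera adjusted p = 0.0204, and an adjusted p of 0.45 with an estimated correlation), Vdac1 being at -0.22 ± 0.06, Mfn2 at -0.16 ± 0.06, Tomm20 at -0.16 ± 0.07 and Tfam at -0.25 ± 0.10; 4 had an unadjusted p under 0.05 and DESeq2 called 1. Of 18 metal transport genes, the copper chaperone gene Atox1 fell (-0.46 ± 0.09, adjusted p = 0.0285), while Atp7a (0.35 ± 0.09), Mt1 (-0.29 ± 0.08) and Slc39a1 (-0.23 ± 0.07) did not pass; the median was -0.11, the camera adjusted p 0.0465 and the adjusted p 0.41 with an estimated correlation. The calls of Pgk1, Bnip3 and Atox1 were lost without any of the control replicates or cKO replicate 1, with adjusted p of 0.175, 0.126 and 0.137 without the last. The glycolysis call was lost without control replicate 1 (adjusted p = 0.0905) or cKO replicate 1 (0.107), the mitochondrial biogenesis call without control replicate 3 (0.134) or cKO replicate 2 (0.0654), and the metal transport call without control replicate 3 (0.136), cKO replicate 1 (0.0833) or cKO replicate 3 (0.0536), or with the length and GC trend removed (0.0573), where the median was -0.117 (quartiles -0.201 and 0.036) against -0.113 (-0.189 and 0.004), so that the shift was no smaller and the cause of the lost call was not tested; over all alternatives these lists reached 0.000365 to 0.484, 0.00759 to 0.45 and 0.0156 to 0.41. Of 24 ATF4 targets and 25 p53 and apoptosis genes, 0 were called with edgeR, 4 and 7 had an unadjusted p under 0.05 and DESeq2 called 1 and 2; neither list was called (0.912 and 0.333). Among the former Atf4 (-0.28 ± 0.07) and Wars (-0.19 ± 0.07) were lower and Atf3 (0.27 ± 0.11) and Psat1 (0.25 ± 0.11) higher. Among the latter Casp8 (-0.21 ± 0.06), Fas (-0.37 ± 0.11) and Cdkn1a (-0.23 ± 0.08) were lower and Gadd45a (0.35 ± 0.13) higher. None of these genes passed.

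Adjusted over the list alone, 3 rose and 8 fell in glycolysis, 2 rose and 5 fell in hypoxia, 1 rose and 3 fell in autophagy, 1 fell in mitochondrial biogenesis, 1 rose and 4 fell in metal transport, and 0 changed among ATF4 and p53 targets.

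Of 20 genes of lipid uptake and cholesterol efflux, 9 rose and 0 fell, and 11 rose when adjusted over the list alone. Abcg1, a sterol exporter, rose from 133 ± 5.66 to 185 ± 9.29 CPM (0.47 ± 0.06, adjusted p = 0.00219), the fatty acid binding protein gene Fabp4 from 21.5 ± 2.19 to 34.7 ± 2.82 CPM, the desaturase gene Scd2 from 79.1 ± 0.95 to 109 ± 10.6 CPM and the sterol exporter gene Abca1 from 496 ± 28.7 to 607 ± 0.93 CPM. The list's median was 0.23, with a camera adjusted p of 4.23e-12 and an adjusted p of 0.309 with an estimated correlation. With the length and GC trend removed, 6 rose, at a median of 0.21 and a camera adjusted p of 1.84e-11. Of 23 cholesterol synthesis genes, 2 rose, including Dhcr7, a sterol reductase (0.59 ± 0.08), and 0 fell, while Mvd (0.36 ± 0.10) did not pass, and 4 rose when adjusted over the list alone; that list was not called (median 0.05, adjusted p = 0.0943). The calls of Abcg1, Fabp4 and Dhcr7 held without any library in turn, whereas those of Scd2 and Abca1 were lost without control replicate 1 or cKO replicate 1 (0.161 for Abca1 without the latter), and that of Abca1 without control replicate 3 or cKO replicate 2.

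Proliferation genes leaned higher in cKO cells. Of 31 genes of G2 and M phase, 30 had positive log2 fold changes, 2 rose and 0 fell, and 12 rose when adjusted over the list alone. Mki67 rose from 99.3 ± 10.3 to 140 ± 8.60 CPM (adjusted p = 0.00753) and Cenpf, a kinetochore gene, from 15.0 ± 2.94 to 22.7 ± 0.77 CPM (adjusted p = 0.0316), while Ccna2 (0.38 ± 0.09) and Nusap1 (0.53 ± 0.13) did not pass. The median was 0.29, with a camera adjusted p of 1.39e-10 and an adjusted p of 0.309 with an estimated correlation. Of 31 S phase genes, Uhrf1 rose (0.43 ± 0.09, adjusted p = 0.0361) and 0 fell, Mcm5 was at 0.25 ± 0.08, Gins2 at 0.63 ± 0.25 and Mcm10 at 0.34 ± 0.15, and 1 rose when adjusted over the list alone; that list was not called (median 0.10, adjusted p = 0.0636). The calls of Mki67, Cenpf and Uhrf1 were lost without control replicate 1 or 3 or cKO replicate 1, with adjusted p of 0.0815, 0.181 and 0.173 without the last, those of Cenpf and Uhrf1 also without cKO replicate 2, and that of Uhrf1 without cKO replicate 3. The S phase list was called without cKO replicate 1 (0.0293) or 3 (0.024) and with the length and GC trend removed (0.0313), against a range over all alternatives of 0.024 to 0.484.

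Some genes of the inflammatory and macrophage lists passed the test, where 2.42% of all tested genes were called. Of 27 genes of the inflammatory and NF-kB list, 0 rose and 3 fell, and 7 fell when adjusted over the list alone: Il1rn, the interleukin-1 receptor antagonist (-0.47 ± 0.07), Tlr2 (-0.33 ± 0.07) and Nfkbia passed over all genes, and Nlrp3 (-0.30 ± 0.07) did not. Il1rn and Nfkbia restrain inflammatory signalling. The median was -0.30, with a camera adjusted p of 0.000772 and an adjusted p of 0.45 with an estimated correlation; without control replicate 2 the adjusted p was 0.338, against a range over all alternatives of 4.63e-06 to 0.45. That library stood apart, at a mean of 0.62 relative to the control mean against -0.46 and -0.155 in the other controls, and cKO replicates 1 to 3 were at 0.06, -0.34 and 0.16. Without it the median was -0.05. Among 25 macrophage identity genes, 3 rose and 2 fell: Ccr2, Cd36, a scavenger receptor (0.49 ± 0.10), and Vsig4, a complement receptor chosen after its values were seen (1.05 ± 0.25), rose, and Lyz2 and C1qa, a complement component (-0.45 ± 0.08), fell. The fall of Lyz2, whose locus carries the Cre insertion, cannot be told apart from an effect of that insertion. Of 17 genes of alternative activation, 3 rose: the folate receptor gene Folr2 (0.95 ± 0.15), Egr2 (0.48 ± 0.09) and the lipid-sensing nuclear receptor gene Pparg (0.51 ± 0.12), while Chil3 (0.97 ± 0.28) did not pass. Neither list was called (0.985 and 0.109), and 7 rose and 4 fell in the former and 5 rose in the latter when adjusted over the list alone. None of 33 interferon response genes was called with edgeR or DESeq2, 1 had an unadjusted p under 0.05, and Stat2 was at 0.19 ± 0.08, Oas3 at 0.24 ± 0.11, Xaf1 at 0.21 ± 0.17 and Bst2 at -0.14 ± 0.11. That list was not called (camera adjusted p = 0.432), but reached 6.86e-06 without control replicate 2, against 0.914 at most over all alternatives. None of 9 MHC class II genes was called with edgeR, while 3 had an unadjusted p under 0.05 and DESeq2 called 3; the list was not called (0.313), with Ctss (0.32 ± 0.08) and Cd74 (-0.36 ± 0.09) having the smallest p. H2-Aa was at -0.34 ± 0.10 and H2-DMa at 0.23 ± 0.11. Of 20 immediate early and stress genes Egr2 was the only call (list adjusted p = 0.0875, but 0.0109 without control replicate 3 and 0.0198 without cKO replicate 2, over a range of 1.65e-06 to 0.574), with Fos at -0.29 ± 0.09 and Hspa1a at -0.41 ± 0.13. The call of Il1rn held without any library in turn. That of Folr2 was lost without control replicate 1 (0.079), and those of Tlr2, Egr2, Pparg, Cd36, C1qa and Vsig4 were lost in 3 to 6 fits, all of them without control replicate 1 or cKO replicate 1. Adjusted over the list alone, 0 interferon genes changed, 1 MHC class II gene rose and 2 fell, and 1 immediate early gene rose and 4 fell.

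**Figure D3:**
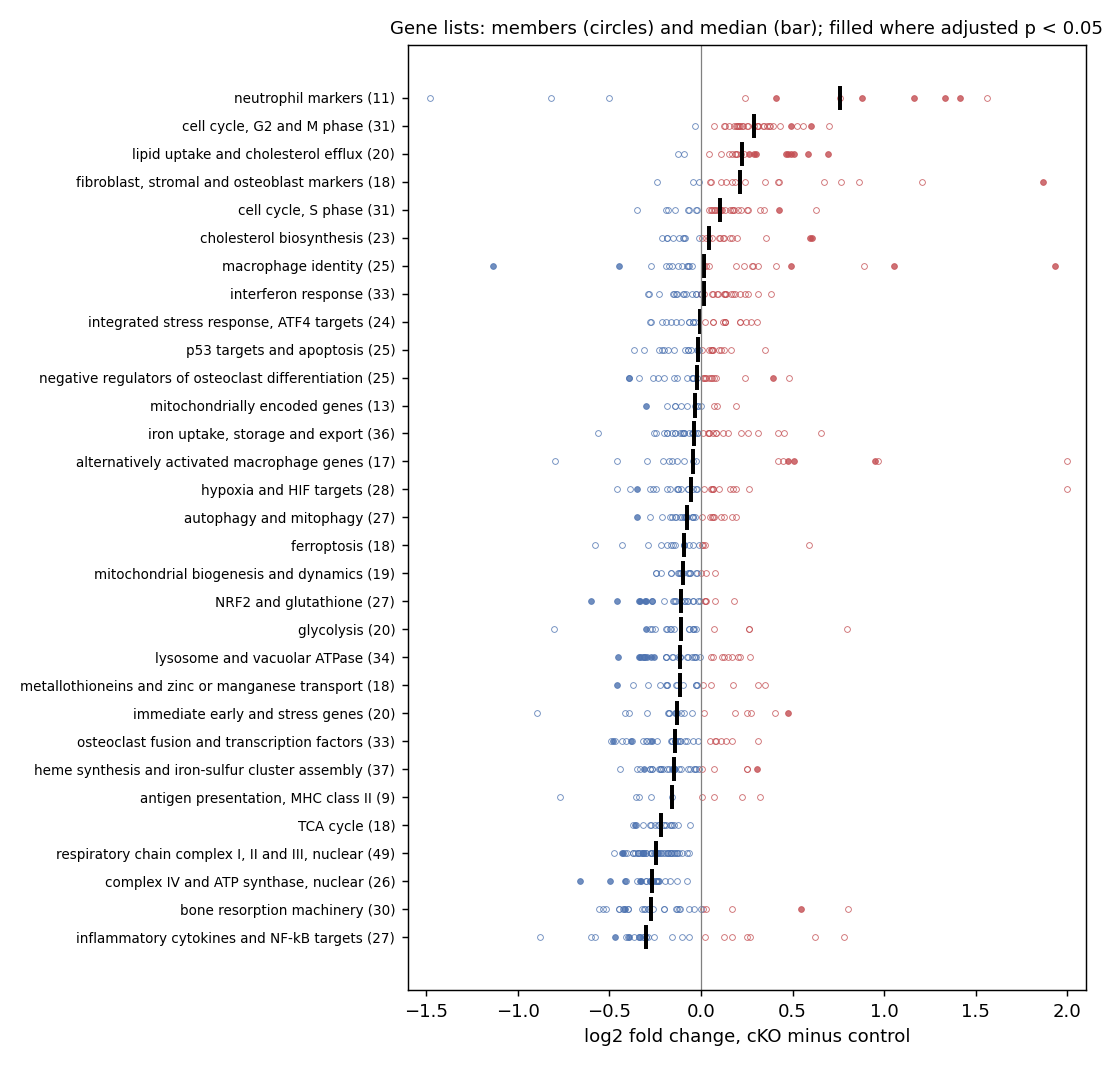
Log2 fold changes (cKO minus control) of the members of the 31 lists with at least 9 measured genes, with circles for genes, filled where the adjusted p is below 0.05, and a bar at each list's median. Lists are ordered by median, from -0.30 for inflammatory genes to 0.76 for neutrophil markers; a few values lie beyond the axis limits and are drawn at them.

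Lists of markers of other cell types were called for neutrophils and stroma only. Of 11 measured neutrophil markers, 5 rose and 0 fell: Ngp, Ltf, S100a9, S100a8 (0.88 ± 0.20, adjusted p = 0.0401) and Csf3r, a receptor gene chosen after its values were seen (0.41 ± 0.09). That list had a median of 0.76, with a camera adjusted p of 2.79e-09 and an adjusted p of 0.274 with an estimated correlation. Control replicate 1 was low, at a mean of -0.566 relative to the control mean against 0.428 and 0.137 in the other controls. The cKO libraries were at 0.594, 0.492 and 0.533. Without control replicate 1 the list's median was 0.504. Of 18 fibroblast, stromal and osteoblast markers, 1 rose and 0 fell: Alpl, the tissue-nonspecific alkaline phosphatase, which osteoblasts and neutrophils express, went from 0.64 ± 0.31 to 2.32 ± 0.42 CPM (adjusted p = 0.0268). The list's median was 0.21, with a camera adjusted p of 0.00036, an adjusted p of 0.45 with an estimated correlation and 0.138 without cKO replicate 2, over a range of 1.55e-09 to 0.45. These markers had long transcripts, with a median of 5482 bp, and the list's median was 0.13 with the length and GC trend removed (0.00668). Of 8 dendritic cell markers, Itgax, the integrin CD11c, which macrophages also carry, rose from 339 ± 32.1 to 539 ± 34.8 CPM (0.67 ± 0.08), and of 5 megakaryocyte markers Pf4 fell (-0.58 ± 0.12); these lists were not called (0.0973 and 0.602), except that of dendritic markers with the replicate block (0.0343) and both with fry for changes in either direction (0.00349 and 0.00582). None of the 4 erythroid, 3 B cell, 3 T and NK cell, 6 endothelial and 5 mast cell markers tested was called with edgeR or DESeq2, 1 erythroid marker had an unadjusted p under 0.05, and the camera adjusted p of these lists was 0.726, 0.409, 0.932, 0.735 and 0.602. The endothelial list had a median of 0.20, near that of the stromal list. Adjusted over the list alone, 6 neutrophil and 6 stromal markers rose, 1 dendritic marker rose, 1 megakaryocyte marker rose and 1 fell, and 0 changed in the 5 lists without a call. The calls of S100a8, Alpl, Csf3r and Pf4 were lost without control replicate 2 or cKO replicate 1, with adjusted p of 0.186, 0.173, 0.213 and 0.186 without the latter, whereas that of Itgax held.

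Of the 38 lists, 17 were called with camera, 4 higher and 13 lower. None was called with an estimated correlation, where the smallest adjusted p was 0.274, or with fry for a shared direction, where it was 0.062, while fry for changes in either direction called 29. Mean levels per library overlapped between the genotypes in 5 of the 17 lists, those of osteoclast fusion and transcription factors, bone resorption, glycolysis, ferroptosis and inflammatory genes, and were separate in 12. Median, mean and camera direction differed in sign for some uncalled lists, among them macrophage identity, with a median of 0.02, a mean of 0.13 and a downward direction, and alternative activation, with a median of -0.04, a mean of 0.27 and an upward direction. The others were hypoxia, iron handling, ATF4 targets and the erythroid, T and NK cell, mast cell and megakaryocyte markers.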

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

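The fit with the length and GC trend removed was chosen after the data were seen; the other alternatives were planned. Slc11a2 and Lyz2 were called in every alternative run, at log2 fold changes of -0.52 to -0.44 and -1.18 to -1.06 with a library left out. The 407 calls became 874 with DESeq2 (430 higher, 444 lower) and 704 with sample weights (350 higher, 354 lower, 100 at least 2-fold); 386 and 401 of the 407 genes were among them. The stricter filter left 36 genes changed at least 2-fold in place of 61. With a library left out, calls ranged from 59 to 624, higher genes from 39 to 313, lower genes from 20 to 311 and genes changed at least 2-fold from 24 to 87; fewer libraries also mean less power, and the cause was not tested. With the length and GC trend removed, 381 genes were called, 306 of them shared. The number of lists called, 17, became 0 with an estimated correlation, 0 with fry in 1 direction and 29 with fry in either direction. Of 92 other genes that were called, 72 were called in all 8 alternatives that keep every library and 26 without any library in turn; 65 were lost without cKO replicate 1, 58 without control replicate 1, 54 without control replicate 3, 35 without control replicate 2, 34 without cKO replicate 2 and 6 without cKO replicate 3. Only Fth1 and Atp6v0d2, neither called, changed sign: Fth1, at -0.08 to 0.055 with a library left out, to 0.002 with sample weights, 0.038 with the trend removed, and 0.033 and 0.055 without control replicate 1 or cKO replicate 3; Atp6v0d2, at -0.081 to 0.07 with a library left out, to 0.001 with the stricter filter, 0.019 with the trend removed, and 0.07, 0.012 and 0.027 without control replicate 3, cKO replicate 1 or cKO replicate 2.

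Over all genes the replicate numbers showed no pairing. Deviations of same-numbered libraries had correlations of -0.025, -0.018 and -0.004, and 0 of the 6 libraries correlated best with its own number. Some osteoclast genes were highest in replicate 3 of both control and cKO cells: Acp5 (3312 and 2401 CPM), Mmp9 (7384 and 5813) and Ctsk (2398 and 1966). A structure shared by some genes is therefore not excluded. With the replicate number as a block, 673 genes were called, 357 of them lower, and Acp5, Mmp9, Ctsk, Dcstamp and Nfatc1 were among them. The pseudocount, transcript-level and quantile alternatives were not run, since the files hold counts per gene.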

Other observations

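The annotation terms and the tests in this part were chosen after the results were seen, except the comparison with other splits of the libraries, and so were the genes that the report does not name. Among 4722 GO, KEGG and Reactome terms, 17 were enriched among the genes higher in cKO cells and 43 among those lower. The hypergeometric test treats genes as independent, so its p-values can be too small where genes of a term vary together. The estimated correlations within the 2 respiratory chain lists were 0.27 and 0.58. The higher genes held 8 of 50 measured genes of PPAR signaling (hypergeometric adjusted p = 0.0012), among them Lpl, Cd36, Fabp4 and Cyp27a1, a sterol hydroxylase. They held 7 of 35 genes of cholesterol metabolism (0.0012), among them Scarb1, Lpl and Sort1. Extracellular matrix genes were enriched as well, with 11 of 164 (0.0176): Col6a2, a collagen VI chain, rose from 166 ± 5.10 to 262 ± 36.1 CPM, Col6a1 by 0.59 ± 0.08 (SE), Ltbp4 by 1.10 ± 0.19 and Mmp12, the macrophage elastase, by 0.37 ± 0.08 on the log2 scale. As a set the 164 genes had a median of 0.129, or 0.098 with the length and GC trend removed. The list of stromal markers, of which 1 of 18 passed, had a median of 0.21, or 0.13 with the length and GC trend removed, and no call with an estimated correlation (0.45).

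Genes annotated to the inflammatory response were over-represented among the rises, with 16 of 239 (adjusted p = 0.0012), whereas 6 fell. As a set the 239 genes had a median of 0.002 and were not called by camera (adjusted p = 0.704). The 16 included the neutrophil markers S100a8 and S100a9. Clec7a, encoding Dectin-1, rose by 0.57 ± 0.08 (SE, edgeR adjusted p = 0.00565), while Clec4n and Clec4e fell. Tlr8 rose by 0.41 ± 0.07 and Cybb, the catalytic subunit of the phagocyte oxidase, by 0.36 ± 0.06. Among the falls, 19 of 120 measured genes of KEGG oxidative phosphorylation were found (1.22e-09), of which some are vacuolar proton pump genes, and 3 of 10 aldo-keto reductase genes (0.0272), Akr1c12, Akr1c13 (-0.38 ± 0.07) and Akr1b8 (-0.36 ± 0.06). They also held 8 of 48 genes of the Reactome term for iron uptake and transport (0.000187) and 7 of 26 of that for transferrin recycling (4.31e-05), which were vacuolar proton pump genes and, in the former, Slc11a2. The Y-linked genes Ddx3y and Eif2s3y rose by 0.28 ± 0.06 and 0.36 ± 0.07, and Xist, from the inactive X chromosome of female cells, stood at 7.79 and 5.05 CPM in control and cKO cells (-0.62 ± 0.24, adjusted p = 0.227), opposite in sign. The sex of the mice is not given, and Xist and Y-linked genes were detected in all 6 libraries, so a difference in the share of male cells stays open, untested. The call of Col6a2 held without any library in turn, whereas those of the other genes given with values here and above were lost without cKO replicate 1, at adjusted p up to 0.218 for Ddx3y.

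The 6 libraries allow 10 splits into 3 against 3, too few for a share under 0.05. The real split called 407 genes and the highest other split 2; for genes changed at least 2-fold the numbers were 61 and 1, the real split being the only 1 of the 10 as large in both cases. For gene lists, 2 of the 10 splits called as many as the real one: it called 17 lists, and the split that sets control replicates 1 and 3 with cKO replicate 3 against the rest called 19. Every other split called lists too, at least 4 each. The number of lists called with the preset correlation therefore does not set the genotypes apart from the split that called 19.

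The lower level of 75 nuclear respiratory chain genes in cKO cells has technical and cellular explanations. The trend over transcript length argues for part of it, since the median moved from -0.26 to -0.188 when the trend was removed and calls went from 11 to 6. The values below bear on whether it is the whole cause. Every cKO library stayed below every control library, at -0.101 for the highest cKO and -0.08 for the lowest control library. The mean difference was -0.20 (95% interval -0.376 to -0.014). After the removal, however, 10000 random lists matched on transcript length and level still had a median of -0.052. That exceeds the distance between those 2 libraries and that of the interval from 0, so this comparison cannot exclude the trend. The 75 genes, at -0.188, were below the 2.5% point of the random lists, -0.084, but genes are not independent replicates. The lists of these genes are not called with an estimated correlation (0.309 and 0.325). A loss of mitochondria that lowers all mitochondrial transcripts alike stays open. The 13 mitochondrially encoded genes had a median of -0.03, and their mean relative to the nuclear genes was higher in every cKO library, at 0.102 in the lowest cKO and 0.06 in the highest control library. The difference of 0.212 has a 95% interval of -0.037 to 0.46, however, and that of their own mean, -0.298 to 0.191, includes both no change and the nuclear median. The criteria of both tests were set after their values were seen. A smaller share of osteoclasts in the cKO cultures may also contribute, with the bone resorption list at a median of -0.272, but no cell counts were analysed here and it cannot be told apart from a change within cells.

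Among features changed at least 2-fold at 1 CPM or more, 16 were non-coding models, pseudogenes or rows with a shared symbol, 10 higher and 6 lower. Gm42047 (chromosome 8, 121833247 to 121841178) stood at 1.03 CPM in control and 31.6 CPM in cKO cells and Gm42031 at 1.40 and 16.4 CPM, while Erdr1, Gm47283, Gm21860 and Mid1-ps1 at the ends of X and Y were lower. DNA carried along with the Cre insertion is argued against for the set, since 0 of the 16 lie within 20 Mb of Lyz2. None lie that near Slc11a2 either, but both genotypes carried the floxed alleles, so the design does not set them apart there. The windows around both genes held 2.7% of the tested genes. For the X and Y features a lower share of male cells was considered. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had a median of 0.289, all above 0. Features at the ends of X and Y, where Erdr1 is pseudoautosomal, need not follow that share, so no conclusion on them is drawn. Copies of repeated DNA that differ between the mice cannot be told apart from a response to the genotype, as gene counts show neither alleles nor copies. The 3 Y features share a 5 Mb bin (adjusted p = 3.77e-06 in a scan of 536 bins), but their position prompted that scan and 2 of them, Gm21860 and Mid1-ps1, overlap, so it does not bear on the number of copies.

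The rise of neutrophil granule genes in cKO cells was weighed against a carry-over of other marrow cells. A higher share of all other marrow cells remains open, since its markers were near the floor: 34 low markers of erythroid, B, T and NK, mast and megakaryocyte cells had summed CPM that were at most 1.133 times as high in a cKO as in a control library, below the neutrophil list's median fold of 1.69, but 1.33 for B cell markers (127 and 160 reads) and 1.28 for T and NK cell markers (49 and 58 reads). A carry-over of neutrophils remains open too. Of the list's 16 genes, 9 averaged under 2 CPM, while others, such as Mmp8 with 32303 and 36486 reads in control and cKO cells, were abundant. The 9 low members had a cKO over control ratio of 0.967 in summed CPM, with pairwise ratios from 0.589 to 2.98. Summed over libraries, Mpo and Elane went from 143 to 76 and from 52 to 14 reads, and Camp and Cxcr2 from 29 to 82 and from 78 to 126. Single libraries overlapped between genotypes in each of these genes, so no difference is read from them. Elane had 0, 45 and 7 reads in control and 0, 10 and 4 in cKO replicates 1 to 3. Camp had 0, 21 and 8 against 12, 39 and 31. A candidate explanation is a change in granule gene expression within the cultured cells, for which no test was run.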
